A study of Homo sapiens with 2 samples.

How the data were processed

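RNA from exosomes, the small vesicles that cells release into their medium, was profiled on 1-colour long non-coding RNA microarrays. Exosomes of 2 pancreatic cancer cell lines, Hs766t and Hs766t-l2, were compared, with 1 array per line. Sample groups were taken from the cell line given in the labels. The source name of the first sample spells the line with another number, and the cell line field was followed. Per the labels' protocols, cells grew in medium with exosome-depleted serum, ribosomal RNA was removed, and the remaining RNA was amplified by random priming along the whole transcript and labelled with Cy3.

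Per the file headers, both arrays were read in the same scan of 1 slide, and spots were quantified with Agilent Feature Extraction 11.0.1.1. The deposited intensity values of each spot are its processed signal, its signal after background subtraction, and the median pixel brightness of the spot and of its local background, on a linear scale and not scaled between arrays. On the Hs766t-l2 array, Feature Extraction had also divided the signals by a fitted surface (multiplicative detrending), which changed single signals by factors of 0.767 to 1.27. On the Hs766t array the processed signal equalled the background-subtracted one. A second deposited table holds the authors' log2 values for 58944 probes. Its scale was found by setting each column against the scanner values of the same array: over probes well above background on both arrays, the ranks within an array were the same (Spearman rho of 1 for each), the slope on log2 processed signal was 1.02 for Hs766t and 0.979 for Hs766t-l2, and the sorted columns differed by at most 0.0894. The values thus have the form of quantile-normalized log2 signals with a floor near 5.00 signal units, at which 72.1% of the Hs766t values and 70.4% of the Hs766t-l2 values lay. The medians of the columns were 2.32 and 2.32, and no gene centring was seen. How the authors made this table is not given in the sources used here.

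Each array held 61184 spots, of which 58945 were probes with a manufacturer's number. Of these, 13 with a non-uniformity or population outlier flag on either array were left out, and 58932 were kept. No kept probe was saturated. The probe numbers are not paired with genes in the files used here, and 0 of them matched the gene table (RefSeq annotation of GRCh38.p14), so transcript names, coordinates and the division into coding and non-coding RNA were not analysed here. The comparisons, the alternatives other than those named below as added, the gene lists and the rule for named genes were fixed before the data were examined, while the tests of explanations were not. Of the 23 gene lists, 20 had no gene-named probe, and no test of a list was made. Gene names were available for 20 probes whose systematic name is a RefSeq messenger RNA accession, all 20 of which matched the gene table, and for control probes whose own names give GAPDH or PGK1. These probes were spotted repeatedly, mostly 10 times, and were analysed apart from the numbered probes. The accession probes and 60 probes named as negatives are not marked as controls in the files, but they were left out of the counts of numbered probes.

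The processed signals were put on the log2 scale, and the 75th percentile of each array was subtracted. Since most probes were not well above background, the percentile was taken over probes well above background on both arrays. It was 6.73 for Hs766t and 7.17 for Hs766t-l2 in log2 units, so the Hs766t-l2 array was 1.36 times brighter before scaling. Differences are Hs766t-l2 minus Hs766t. A difference was counted when it reached 2-fold. A probe not well above background on 1 array has only a bound there: its fold is given as at least the bright value over the higher of the dim probe's own value and the lowest signal of any probe well above background on the dim array (6.99 signal units on Hs766t and 6.76 on Hs766t-l2, each scaled as above, to -3.92 and -4.41).

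With 1 array per line there is no replicate of culture, exosome isolation, labelling or array, so no test was made and no p-value is given, and the number of arrays limits the precision. Errors are technical only. The SD over repeated spots of 1 probe had a median of 0.172 log2 units on Hs766t and 0.191 on Hs766t-l2, which gives 0.257 for a difference. These medians rest on 9 probes on Hs766t and 11 on Hs766t-l2, none of them a numbered probe. For numbered probes, which have 1 spot each, the error printed is Feature Extraction's own error estimate carried over to the difference. Shares of probes have 95% Wilson intervals, which cover counting error only.

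The rule for named genes was to name the genes with the largest differences in each direction, those with the largest bounds, and members of the fixed lists. It could be applied only to gene-named probes, so PFN1, GAPDH and PGK1 are named as measured. For the numbered probes, 1 probe with the largest difference among probes at or above the median mean signal and 1 with the largest bound are given in each direction, a narrowing of the rule chosen after the values were seen. The counting steps were tested on simulated data made from the Hs766t signals with a spot SD of 0.2 log2 units: for Hs766t-l2 against Hs766t, 100% of 200 probes changed by 4-fold and 56.0% of 200 changed by exactly 2-fold were recovered, and in these simulations 8 and 1 of 13674 unchanged probes were counted. With 8-fold changes 100% were recovered and 12 unchanged probes were counted. Changes were placed only in probes above the median signal, evenly in both directions, and no detection filter was applied. The measured differences had an SD of 0.654 log2 units. The simulation therefore checks the counting steps only and gives no error rate for the counts below.

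The alternatives were quantile normalization, centring on the median, the 75th percentile over all probes, a loess curve on the mean signal (span 0.3), normexp background correction with offset 50 on the median spot and background signals (the mean spot signal was not used here), the authors' table, another detection call, other filters on dim probes, and other sizes of difference. Counting genes in place of probes, the choice of the brightest probe of a gene, and all alternatives for the lncRNA of the series title and for gene lists were not run, because the probes are not paired with genes. Signals before multiplicative detrending, and keeping the probes with outlier flags, were added after the data were seen, as were the tolerances, which are the technical error given above for a single probe and 0.1 log2 units for a median. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, were used.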

Results

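To compare the RNA that 2 pancreatic cancer cell lines release in exosomes, exosomal RNA of Hs766t and of Hs766t-l2 was hybridised to 1 long non-coding RNA array each. The series was collected around the exosomal lncRNA SOX2OT, a transcript that overlaps the pluripotency gene SOX2. Its probes, and those of SOX2, were not analysed here because the numbered probes carry no transcript names. Without replicate arrays, every difference below describes these 2 arrays and was not tested against the spread between cultures.

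A similar share of the probes was detected with exosomes of each line. On the Hs766t array 13863 of 58932 probes were well above background, or 23.5% (95% Wilson interval 23.2 to 23.9%), and on the Hs766t-l2 array 13555 were, or 23.0% (22.7 to 23.3%). Of these, 12149 probes were well above background on both arrays, 1714 on the Hs766t array only and 1406 on the Hs766t-l2 array only, while 43663 (74.1%) were above background on neither. Of the 100 brightest probes, 94 were the same on both arrays, as were 926 of the 1000 brightest.

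The exosomal profiles of the lines were similar over most measured probes. Across the 12149 probes measured on both arrays, log2 signals correlated with a Pearson r of 0.967 and a Spearman rho of 0.925. These are correlations across probes, which are not independent replicates. With no replicate or unrelated sample, how high such values run between other samples on this platform is not known here. After scaling, 11327 probes (93.2%) lay within 2-fold of each other. The median difference was 0.06 on the log2 scale, and the middle part of the distribution, from its lower to its upper quartile, ran from -0.29 to 0.31. Repeated spots of a few probes, none of them numbered, give an SD of 0.257 for a difference. Of the measured probes, 1403 (11.5%) lay beyond 3 times that SD.

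Differences of 8-fold and more were mostly towards lower signal in Hs766t-l2 exosomes. At least 2-fold higher in Hs766t-l2 were 241 probes (1.98%), and at least 2-fold lower were 581 (4.78%). Of these 822 probes, 803 differed by more than 3 times Feature Extraction's own error for that probe. This adds little, because the median of that error over the measured probes was 0.227 log2 units. For a typical probe 3 times the error is thus smaller than the 2-fold cut itself, and a counted probe passes by construction. The balance at 2-fold depended on which probes set the scaling. Centring on the median of probes measured on both arrays gave 270 higher and 524 lower. With the 75th percentile taken over all probes, which moved the median difference from 0.06 to 0.31, 485 probes were higher and 386 lower, so that 44.3% of the counted probes were lower against 70.7% in the main scaling. At larger sizes the lower probes outnumbered the higher ones both in the main scaling and with all probes. At 8-fold, 12 probes were higher and 51 lower in the main scaling, against 19 and 42 with all probes. At 16-fold the counts were 3 and 26 against 3 and 24.

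**Figure D1:**
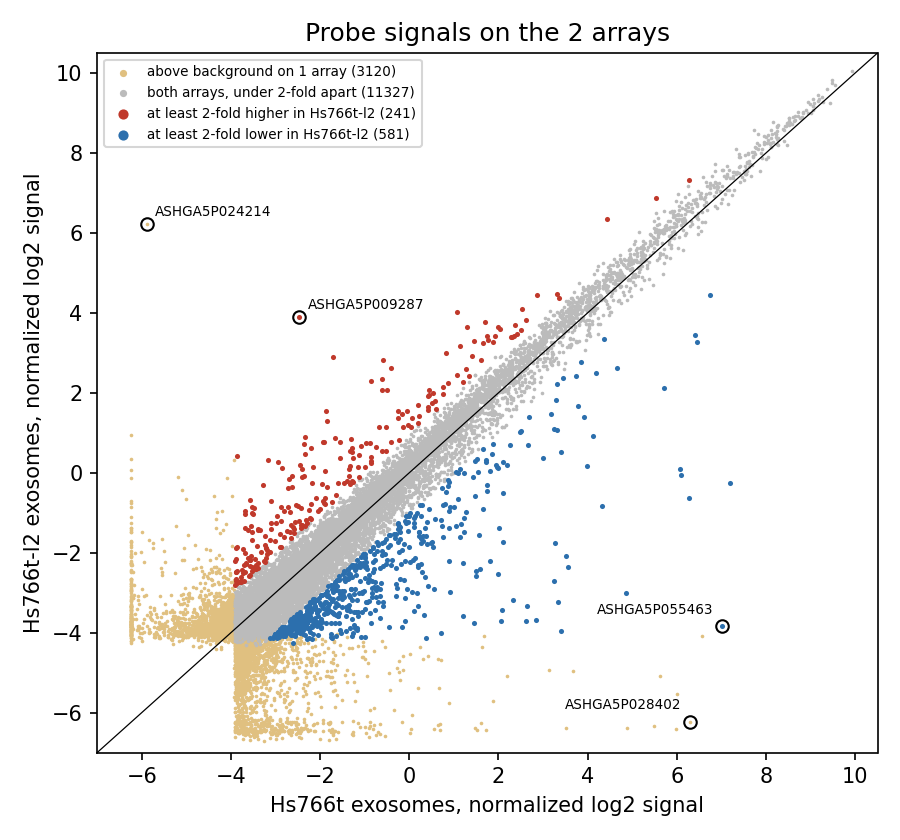
Normalized log2 signal of each probe in exosomes of Hs766t (horizontal) and Hs766t-l2 (vertical), 1 point per probe above background on at least 1 array, with the line of equal signal. Most of the 12149 probes measured on both arrays lie near the line, 241 lie at least 2-fold above it and 581 at least 2-fold below it, and the 4 probes named in the text are circled.

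**Figure D2:**
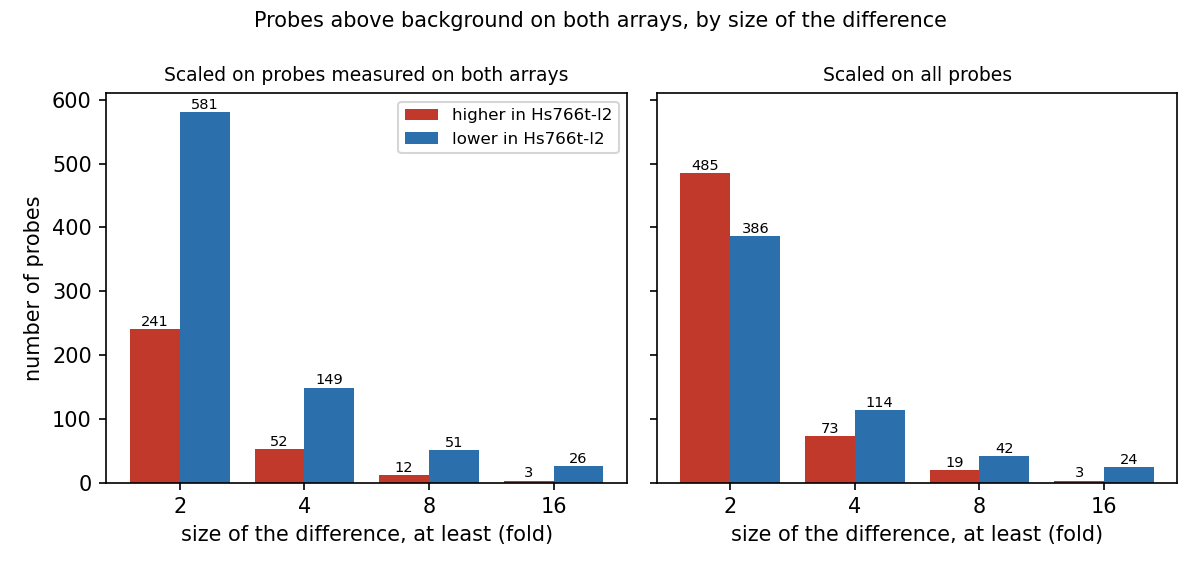
Number of probes, among those above background on both arrays, that were higher or lower in Hs766t-l2 exosomes by at least 2-, 4-, 8- or 16-fold, for 2 ways of scaling the arrays. The 2-fold balance turns with the scaling, from 241 higher and 581 lower to 485 and 386, while at 16-fold the lower probes lead in both (26 and 24 against 3 and 3).

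The counts also differed with brightness. After scaling, the lowest signal well above background was -3.92 on Hs766t and -4.41 on Hs766t-l2, so near these limits the requirement of signal on both arrays admits lower probes more readily than higher ones. Among the 3037 brightest probes measured on both arrays, 70 were at least 2-fold higher and 78 at least 2-fold lower, around a median difference of 0.22. In the next group of 3037 by brightness, 80 were higher and 167 lower, and in the one after it 64 were higher and 185 lower. Among the 3038 dimmest, 27 were higher and 151 lower, around a median of -0.11.

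Single probes differed far more than the rest in each direction. Probe ASHGA5P055463 fell from the bright end of the Hs766t array, at 13580 signal units, to 10.1 on the Hs766t-l2 array, a log2 difference of -10.84 ± 0.31 (Feature Extraction error), and of -7.92 with normexp background correction. Probe ASHGA5P028402 gave 8338 signal units on Hs766t and was not well above background on Hs766t-l2, which made it at least 1679-fold lower. In the other direction, probe ASHGA5P009287 gave 19.1 signal units on Hs766t and 2129 on Hs766t-l2, a log2 difference of 6.36 ± 0.23, and of 4.39 with normexp. Probe ASHGA5P024214 was not well above background on Hs766t and gave 10782 signal units on Hs766t-l2, at least 1134-fold more. The transcripts behind these probes are not named in the files used here.

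Probes above background on 1 array only were mostly close to the detection limit. Of the 1714 seen only with Hs766t exosomes, 622 (36.3%) were at least 2-fold and 42 at least 16-fold higher there. Of the 1406 seen only with Hs766t-l2 exosomes, 143 (10.2%) were at least 2-fold and 5 at least 16-fold higher there. These counts are not directly comparable, because the scaled detection limit is lower on Hs766t-l2 (-4.41 against -3.92). With a limit of -3.92 there, bounds in the first set would be smaller for probes whose scaled Hs766t-l2 value lies below -3.92. For 390 of these 1406 probes the scaled signal did not exceed the scaled detection limit of the Hs766t array, so they have no fold.

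Few of the human gene-named messenger RNA probes gave signal in exosomes of either line, and those that did differed by less than 2-fold between the lines. PFN1 (NM_005022), which encodes the actin-binding protein profilin, was above background on all 10 spots of both arrays. Its mean signal over 10 spots was 77.0 with Hs766t and 127.6 with Hs766t-l2 before scaling, and the scaled log2 difference was 0.29 ± 0.18 (SD of a difference of single spots). It stayed positive under the other scalings and the other background correction run for it, between 0.14 and 0.54. Its 0.29 lay within the quartiles of all measured probes (-0.29 to 0.31), so the kept sign shows no rise particular to PFN1. GAPDH, a glycolytic enzyme, differed by 0.26 ± 0.25 at probe Human-GAPDH_5, and by -0.03 with normexp background correction. The 0.26 was about the size of the spread of single spots, which is wider than the technical error of a mean over 10 spots. PGK1, another glycolytic enzyme, differed by -0.87 ± 0.32 at probe Human-PGK1_3, which is 1.83-fold lower in Hs766t-l2 exosomes and larger than the spot spread. It stayed negative under the other scalings and the other background correction run for it, between -0.94 and -0.53. Normexp moved the median difference of all measured probes from 0.06 to -0.13.

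Probes of the same gene did not all give signal. The further probes Human-GAPDH_3 and Human-PGK1_5, and the accession probes of GAPDH (NM_002046) and PGK1 (NM_000291), had no spot well above background on either array. Of the 20 accession probes, 1 (PFN1) was above background on every spot of both arrays, which is 5% (95% Wilson interval 0.888 to 23.6%), and 18 had no spot above background on either array. Of the fixed lists, the cytosolic ribosomal proteins had RPL10, RPLP1 and RPS18 among these 18 and the nuclear respiratory chain genes had COX4I1, and the glycolysis list had the accession probes of GAPDH and PGK1. The 18 also included the actin genes ACTB and ACTG1. Their mean signals lay between 1.39 and 4.24 signal units. RACK1, a component of the small ribosomal subunit, was at the limit, with 5 of 9 spots above background for Hs766t and 1 of 9 for Hs766t-l2.

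**Figure D3:**
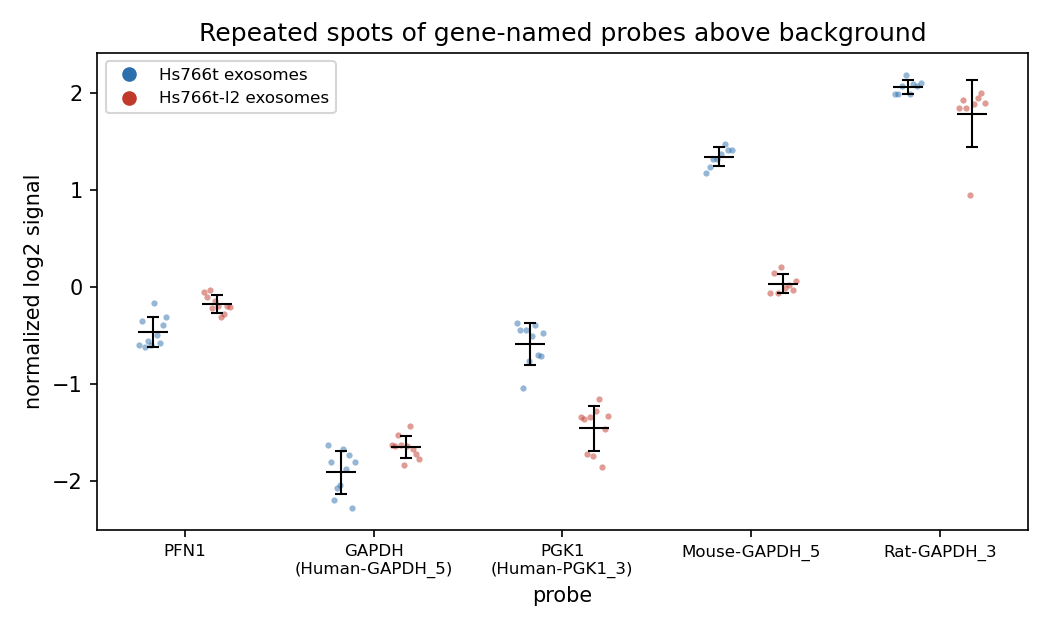
Normalized log2 signal (vertical) of repeated spots of the human gene probes PFN1, GAPDH and PGK1 and of 2 rodent-named GAPDH control probes (horizontal), for exosomes of Hs766t and Hs766t-l2, with points for spots and bars for the mean ± SD over 8 to 10 spots. PGK1 and Mouse-GAPDH_5 lie lower with Hs766t-l2 (by 0.87 and 1.31), PFN1 and Human-GAPDH_5 slightly higher (by 0.29 and 0.26, the latter -0.03 with normexp).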

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

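Of the tests in this part, the one on a damaged area and the one on the scaling constant at 2-fold were chosen after the result was seen, and the test on detection limits was planned with each array's own limit but run with 1 common limit. The control probes below are set apart because they carried signal on all their spots of at least 1 array although they are no part of the comparison of exosomes.

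Signal appeared on probes named as negative controls. Of 60 such probes, each spotted 10 times, 54 had no spot well above background on either array, and 4 were above it on every spot of at least 1 array. Negative009 gave a mean of 42.0 signal units on Hs766t and 74.6 on Hs766t-l2, Negative012 gave 9.63 and 13.9, Negative038 gave 7.02 and 11.5, and Negative035 gave 2.97 and 37.2 over 9 spots, its other spot (10.97 and 116.2) being left out of the means for an outlier flag. After scaling, the log2 differences were 0.39, 0.08 and 0.29 for Negative009, Negative012 and Negative038. Negative035 differed by 3.31 ± 1.06, or 9.92-fold. A probe named as a negative can thus differ by more than 8-fold between these arrays, and the cause was not tested. Light from a bright neighbouring spot does not account for the signal on these 4 probes. Of their 67 spots above background, the spot with the outlier flag included, 61 (91.0%) had no neighbour over 1000 signal units. Hybridisation of labelled RNA to these sequences stays open, since the probe sequences were not used here, and no biological explanation was tested.

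Some GAPDH control probes named for rodents gave signal with these human exosomes, and others did not. Mouse-GAPDH_3 was above background on 4 of 10 spots for Hs766t and 1 of 10 for Hs766t-l2. Rat-GAPDH_5 and the rodent-named PGK1 probes had no spot above background on either array. Mouse-GAPDH_5 gave 268.4 signal units on Hs766t and 147.4 on Hs766t-l2, a scaled log2 difference of -1.31 ± 0.14, while Human-GAPDH_5 differed by 0.26 ± 0.25. Rat-GAPDH_3 gave 442.3 and 507.4, a scaled difference of -0.28 ± 0.35. Among spike-in control probes, (+)E1A_r60_a22 gave 147.7 and 214.0 and (+)E1A_r60_a20 gave 14.8 and 18.7 before scaling. Their scaled log2 differences were 0.09 ± 0.14 and -0.10 ± 0.28. These were 2 of the 10 E1A probes, and the others had no spot above background on either array. ERCC-00062_278, 1 of 12 ERCC probes, gave 10.8 and 16.3, and the control probe ETG05_66023 gave 21.8 and 20.9. The scaled differences of these 2 were 0.16 ± 0.29 and -0.51 ± 0.24.

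More probes were far lower than far higher in Hs766t-l2 exosomes. At 2-fold, an intensity-dependent shift is argued against, since after loess the lower probes were still 2.52 times as many as the higher ones. Detrending on 1 array is argued against by a ratio of 2.24 without it. Damage confined to 1 block of the array is argued against by the fullest of 96 blocks holding only 2.58% of the lower probes. Uneven hybridisation over many blocks could leave no single block so full, and it was not tested. The scaling constant remains as an explanation at 2-fold, because the lowest ratio over 3 constants was 0.796. That ratio came from the 75th percentile over all probes, while the main scaling gave 2.41 and median centring 1.94. Only 23.5% and 23.0% of probes were well above background, so that percentile lay near the detection call. Detection limits stay open at 2-fold for dim probes. Among 3317 bright probes held to the higher of both limits, 180 were lower and 111 higher, a ratio of 1.62. At 8-fold neither the constant, with a lowest ratio of 2.21, nor unequal detection limits, with a ratio of 4.65 among the same bright probes (79 lower, 17 higher), removed the excess; differences of culture, isolation or labelling that go with single samples cannot be separated from the cell lines, and a difference between the lines themselves stays open and untested.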

How the results depend on the processing

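The main counts were 241 probes at least 2-fold higher and 581 at least 2-fold lower in Hs766t-l2. Signals before detrending, keeping probes with outlier flags and the tolerances for medians and single probes were chosen after seeing the data. Counts stayed within 1.5 times of the main ones with quantile normalization (297 and 494), median centring (270 and 524), loess (233 and 586), the authors' table (297 and 493), signals before detrending (259 and 579) and probes with outlier flags kept (246 and 590). Of the 241 and 581 probes, 230 and 478 were also counted in the authors' table. Higher and lower counts moved further with the 75th percentile over all probes (485 and 386, which turned the balance), normexp (86 and 144, which changes the signal column, the background correction and an added offset of 50 together), the positive and significant flag (1204 and 2296), probes at or above the median mean signal only (150 and 245, from fewer probes) and no filter on dim probes (2320 and 5721, from more). A size of 1.5-fold gave 937 and 1489, and of 4-fold 52 and 149. With the positive and significant flag, 50.5% of probes were detected on Hs766t and 47.7% on Hs766t-l2, with 6805 and 5165 on 1 array only. Beyond what fewer or more probes give by construction, the cause was not tested. The median difference of 0.06 moved by more than 0.1 with the 75th percentile over all probes (0.31), normexp (-0.13) and no filter (-0.16). Of single-probe differences under the alternatives, 8 moved by more than their technical error and 31 did not; the difference at Human-GAPDH_5 changed sign with normexp (-0.03). Signals near background limit how well small differences of dim probes can be read. Gene-level counts, gene lists, the lncRNA of the series title and the brightest probe per gene were not run. No paired analysis was possible because each line has 1 array, and no sample could be left out for the same reason.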

Other observations

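The tests in this part on whether neighbouring numbers differ alike were chosen after the result was seen. In the main scaling, 20 probes measured on both arrays were at least 32-fold lower in Hs766t-l2 exosomes and 1 was at least 32-fold higher. The transcripts behind them were not analysed here.

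Several close probe numbers stood among the most strongly lower probes. The hypothesis that probes with neighbouring numbers differ alike did not hold over the probes measured on both arrays as a whole. Pairs with a probe above background on 1 array only were left out, although such probes can be among the most strongly lower ones. The tests therefore cannot decide whether the most strongly lower probes lie close in number. Over 2726 pairs of consecutive numbers measured on both arrays, the correlation across probes was 0.00526, within the range of 100 shuffles of the numbers (-0.0695 to 0.0498). Of such pairs, 11 were both at least 2-fold lower, where the shuffles gave a mean of 6.08 and at most 14. Closeness on the array was tested too, and the median distance of consecutive numbers was 0.977 times that of random pairs. After loess the correlation was 0.00607, which decides nothing about an intensity-dependent shift, because no correlation was there before it.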
